A study of Homo sapiens with 6 samples.

How the data were processed

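RNA from 6 samples of transfected HEK293T cells, 3 per siRNA, was sequenced as poly-A selected dUTP libraries with paired 75 base reads, per the labels' protocols. Per the labels, reads were demultiplexed with CASAVA 1.8.2 and aligned to hg19 with STAR 2.4.0k. Per the file headers, the authors counted reads over exons with HOMER, which merged transcripts of a gene, and compared the groups with edgeR, version 3.6.8 per the labels. The header command shows no strand option, so genes that overlap on opposite strands are uncertain. Genes were called by the authors, per the labels, at an FDR under 0.05 and a log2 fold change over 1.

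The per-library values are a signal: the deposited coverage per gene, scaled by the authors so that each library sums to between 29401170 and 29401184. They are not whole, and each library's values are whole multiples of 1 step (100% of values within 0.1 step). The step was taken to be 1 read end, a reading inferred from the values: 59.2% to 61.0% of values of up to 40 steps are even, and the mean over libraries would then be 29401180 pairs, within the range of the deposited totals. Read pairs and the limit below rest on this reading, while the relative depth of the libraries does not. The deposited log2 fold changes and p-values of the authors' comparison, including their adjusted p-value column, were used only to set beside the values computed here. The table has 26391 rows, of which 4787 were at 0 in all libraries; 841 rows have more than 1 genome position. Read pairs per library run from 8604236 to 36082404, and for a gene with a count of 0 the limit of 3 pairs equals 2.44 to 10.25 deposited units, for counting error only.

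The design was fixed before the data were examined, with edgeR's quasi-likelihood test as the main test on the assumption that the file held counts. Because the file holds scaled values, the main test became limma 3.58.1 (linear model, empirical Bayes with a mean trend, two-sided) on log2(value + 1 deposited unit, 0.034 CPM), after TMM scaling, and edgeR 4.0.16 on recovered reads became an alternative. With it, 2858 genes were higher and 2992 lower on read ends and 2859 and 3009 on read pairs. Fold changes on the log2(value + pseudocount) scale understate those of low genes. Genes were kept by edgeR's filter with a minimum of 10 read pairs, which left 16245, and p-values were adjusted by the Benjamini-Hochberg method over them. CPM are deposited values divided by the TMM-scaled library total, in the usual unit of that name. No label says that replicates came from separate passages, so p-values measure the spread between these samples, which may be technical. No pair of replicates agreed within sampling noise (chi-square per degree of freedom 5.47 to 41.4). The highest values, 31.13 and 41.4, were those of control replicate 2 against control replicates 1 and 3, which stood at 9.44 against each other.

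Genes named in the text follow a rule fixed with the design: the target and 7 decay genes; the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, a mean of at least 1 CPM and groups that do not overlap; and up to 4 members with the smallest p of each of 24 gene lists, also fixed then. Genes outside the rule are said to have been looked up later, and some genes that the rule names are not reported here. The 22 lists with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01 and with the correlation estimated, adjusted over the lists; they were run on the log2 values of the main test in place of the log CPM first intended. With fry, which asks whether members move one way on balance and does not compare them with other genes, 12 lists passed.

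Alternatives chosen beforehand were other scalings (median of ratios, upper quartile, library totals), filters, a pseudocount of 0.1, DESeq2 1.42.0, edgeR's exact test, limma with voom, a replicate block, leaving out the 20 most abundant genes, each library left out in turn, and an adjusted p of 0.01. Chosen as alternatives after seeing the data were edgeR's quasi-likelihood test without a block, the main test first intended, on recovered read ends and on pairs, thinning all libraries to the shallowest, and removal of trends with transcript GC content and length (values for 96.2% of tested genes). Also added then, as a description, each list's median was set beside those of 10000 random lists whose members were drawn within 100 ranks of mean level of its own. Transcript sequences came from GENCODE release 44 mapped to GRCh37, in R 4.3.3 and Python 3.11.15. Counts were simulated for this comparison with 200 genes changed and each gene drawn independently. Over 16145 genes, limma recovered 62.7% of genes changed by 1.5-fold, 89.6% by 2-fold and 95.5% by 3-fold, with 5.2% of calls false. In the data far more genes were called, 35.7% of those tested. Of 100 random lists of simulated genes, 0 had a camera p under 0.05. As simulated genes were not correlated, this does not cover the fixed lists, where the estimated correlation reached 0.389.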

Results

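Messenger RNA levels were measured by poly-A RNA sequencing in HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen. Cells at 50% confluency were transfected either with a pool of 4 siRNAs against LOC550643 or with a non-silencing control siRNA, and RNA was taken 48 hours later. LOC550643 encodes a small protein reported to bind EDC4, a scaffold of the mRNA decapping complex, and the comparison asks whether steady-state mRNA levels differ when the gene is silenced. With a single pool and a single control siRNA, effects of the silencing cannot be told apart from other effects of either. Each group held 3 libraries. The control libraries held 32309964, 33421162 and 36082404 read pairs assigned to genes, as inferred from the values. The LOC550643 siRNA libraries held 35249993, 30739321 and 8604236, so LOC550643 siRNA replicate 3 had the largest counting error of the 6. Among the control libraries, replicate 2 differed most from the others. Fold changes are LOC550643 siRNA over control siRNA throughout, on the log2(value + pseudocount) scale.

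LOC550643, listed under its earlier symbol LINC01420 (NR_015367) and now named NBDY, was reduced in all 3 libraries of the pool. Its level was 52.9 ± 2.88 CPM in the control libraries and 5.74 ± 0.292 CPM in the LOC550643 siRNA libraries (SD, n = 3 each), 0.109 of the control level. The log2 fold change was -3.20 (SE 0.088, limma adjusted p = 6.98e-09), and the authors' deposited table lists -3.18 with an adjusted p of 4.36e-145. The single libraries, control replicates 1 to 3 and then LOC550643 siRNA replicates 1 to 3, stood at 56.2, 50.7 and 51.8 CPM with the control siRNA and at 5.85, 5.96 and 5.41 CPM with the pool. The gene lies on the plus strand of chromosome X at 56755718 to 56844004 (hg19). In the GRCh37 annotation its first exon, 56755676 to 56756022, holds coding sequence, and the second, 56758496 to 56758632, and the third, 56843753 to 56845612, are untranslated. UQCRBP1 is listed on the opposite strand within it.

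The mRNA of EDC4 itself did not pass the test, at 128.6 ± 5.97 CPM in control and 124.0 ± 8.58 CPM in LOC550643 siRNA libraries (log2 fold change -0.05, SE 0.074, limma adjusted p = 0.606). Among the mRNAs of its partners in the 5′ to 3′ decay pathway, EDC3, an enhancer of decapping, rose from 66.4 ± 0.534 to 104.2 ± 4.77 CPM (log2 0.65, limma adjusted p = 4.14e-05). DCP2, the decapping enzyme, was higher by log2 0.40 (limma adjusted p = 0.0195) and its activator DCP1A lower by log2 -0.22 (limma adjusted p = 0.0311). DCP2 overlaps MCC on the opposite strand. Its groups overlapped in the deposited values before TMM scaling. In CPM they stood close, with the highest control library at 153.4 and the lowest LOC550643 siRNA library at 156.4. Both of these calls were lost in some fits with 1 library left out. Without control replicate 1, control replicate 3 or LOC550643 siRNA replicate 3, the adjusted p of DCP2 was 0.0852, 0.066 and 0.0871, and it was 0.0548 with library totals alone. That of DCP1A was 0.0708 and 0.0654 without control replicates 2 and 3, and 0.0754 and 0.0994 without LOC550643 siRNA replicates 1 and 2. DCP1B had a log2 fold change of 0.02 (limma adjusted p = 0.835), the exonuclease XRN1 -0.34 (0.138) and the helicase DDX6 -0.17 (0.116). With library totals alone, DCP1B stood at -0.05 and DDX6 passed at -0.25 (adjusted p = 0.0315). DCP1B was also at -0.004 with upper-quartile scaling, and at -0.015 and -0.016 without control replicate 2 and LOC550643 siRNA replicate 2, and EDC4 was at 0.005 without LOC550643 siRNA replicate 3; none of these passed.

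**Figure D1:**
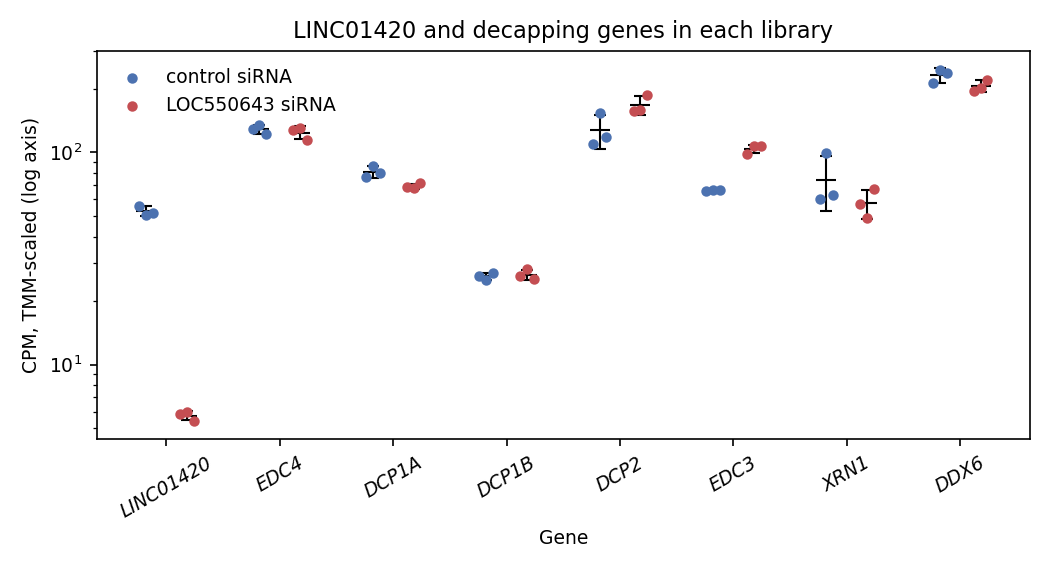
Level of LINC01420 and of 7 decapping and decay genes in each library, in TMM-scaled CPM on a log axis; points are single libraries of the control siRNA (blue) and LOC550643 siRNA (red) groups, and bars give the mean ± SD of 3 libraries. LINC01420 fell from 52.9 to 5.74 CPM, EDC3 rose from 66.4 to 104.2 CPM, and EDC4 stood at 128.6 and 124.0 CPM.

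Across the transcriptome, 2837 of 16245 genes tested were higher and 2956, LINC01420 included, were lower after LOC550643 siRNA (limma adjusted p under 0.05), 35.7% of the genes tested. Most of these differences were small. Of the genes called, 4124 (71.2%) changed by less than 1.5-fold, and the median log2 fold change was 0.39 among genes that rose and -0.49 among genes that fell. Past a log2 fold change of 1, 111 genes were higher and 339 lower. At 8083 genes (49.8%) the groups did not overlap, where chance gives 10%. The first principal component held 58.2% of the variance and separated the groups. The share of higher genes among those called was 49.0%, and with library totals alone in place of TMM scaling it was 34.4% (2081 higher and 3976 lower). With trends in transcript GC content and length removed, it was 59.3% (4167 higher and 2857 lower). The authors' deposited table holds 2450 genes higher and 2778 lower at the same adjusted p, and 117 higher and 400 lower past a log2 fold change of 1. Called in both tables with the same direction were 5050 genes, where independent lists, 2445 higher and 2717 lower of the authors' calls being among the genes tested here, would share 921 in the same direction; both tables rest on the same libraries.

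The genes with the largest falls, among those with a mean of at least 1 CPM and groups that did not overlap, were led by LINC01420. TMEM145, a predicted membrane protein at 42817477 to 42829214 on chromosome 19 (hg19), fell from 16.8 ± 0.647 to 2.18 ± 0.305 CPM (log2 -2.93, SE 0.129, limma adjusted p = 3.35e-07). KCNC1, a voltage-gated potassium channel (chromosome 11, 17757495 to 17799377), fell from 10.9 ± 1.62 to 2.03 ± 0.404 CPM (log2 -2.41, adjusted p = 3.93e-06). NCAN, the brain proteoglycan neurocan, fell by 2.41 and SYN1, the synaptic vesicle protein synapsin I, fell by 2.03 on the log2 scale, both from under 3 CPM in the control libraries. TMEM179, TMEM151A and the sulfotransferase SULT2A1 fell by 2.37, 2.32 and 2.15. PSMB9, an immunoproteasome subunit, fell by 2.26; its row is listed at 8 positions in the genome, so its reads may be shared among copies. LOC100506100 fell by 2.06 and overlaps ZER1 on the opposite strand, and SYN1 overlaps TIMP1, ARAF and MIR4769, so their reads cannot be told apart where strand was not used in counting.

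The genes with the largest rises by the same rule included 3 that were well expressed and are described here. TPM4, a tropomyosin of the actin cytoskeleton (chromosome 19, 16187135 to 16213813), rose from 81.0 ± 2.85 to 321.9 ± 20.7 CPM (log2 1.99, SE 0.071, limma adjusted p = 6.89e-08). G3BP2, a stress granule protein (chromosome 4, 76567953 to 76598667), rose from 110.9 ± 2.09 to 376.5 ± 24.0 CPM (log2 1.76, SE 0.07, adjusted p = 1.4e-07). HABP4, a hyaluronan-binding protein, rose from 22.1 to 76.6 CPM (log2 1.79, limma adjusted p = 5.86e-07). Another 6 were at or below 4.11 CPM in both groups. These were TMEM31 (log2 2.18), SIGLEC10 (2.17), RSPH1 (2.07), LINC01512 (1.78), MIR4751 (1.69) and INHBA, a subunit of activin (1.67). TMEM31 overlaps GLRA4, SIGLEC10 overlaps LOC100129083 and INHBA overlaps INHBA-AS1 on the opposite strand. MIR4751 lies inside ATF5, which also rose, on the same strand, so its reads cannot be told apart from those of ATF5.

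**Figure D2:**
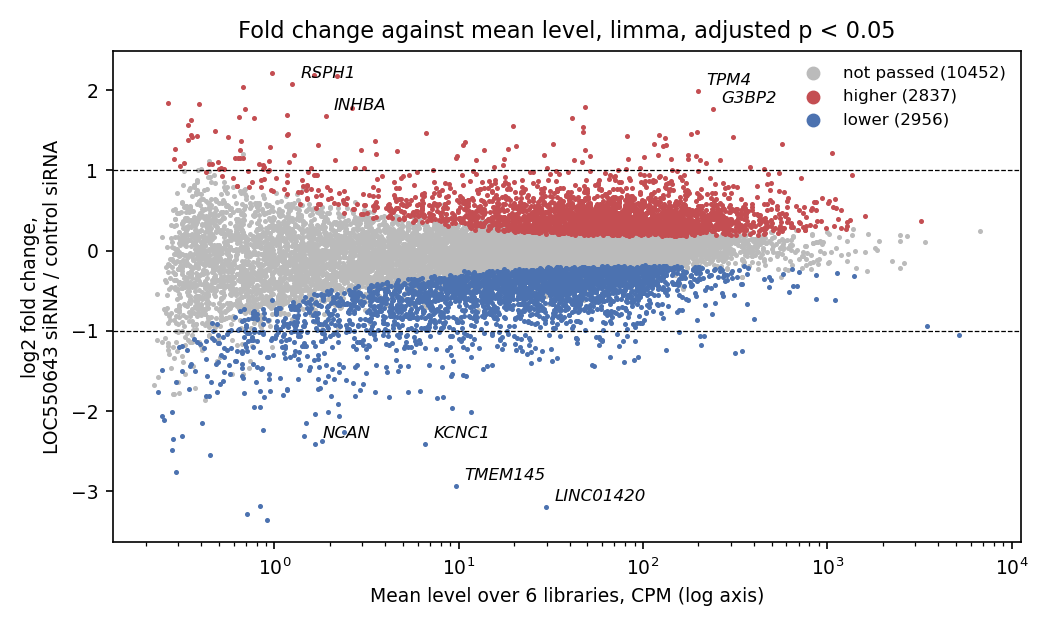
Log2 fold change of LOC550643 siRNA over control siRNA against the mean level over 6 libraries (CPM, log axis) for 16245 genes; red and blue points are the 2837 higher and 2956 lower genes at a limma adjusted p under 0.05, grey points the rest, and dashed lines a log2 fold change of 1 and -1. LINC01420 lies at -3.20, and TPM4 and G3BP2 at 1.99 and 1.76.

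Genes of the mRNA decay machinery changed in both directions, and none of their lists passed the camera test against other genes. With fry, which makes no such comparison, the decapping, deadenylation and nonsense-mediated decay factor lists passed upward (fry adjusted p = 0.0383, 0.0214 and 0.0214). The exosome and RNA interference lists did not pass with fry (0.793 and 0.923). Of 30 decapping and P-body genes, 6 rose, 3 fell and 21 did not pass (camera adjusted p = 0.555); PATL1, a decapping activator, rose by log2 0.49 and the decapping-type hydrolases NUDT16 and NUDT3 by 0.43 and 0.28. Of 20 deadenylation genes 5 rose and 3 fell (adjusted p = 0.166), among them RQCD1 (0.37), BTG1 (0.33) and TOB2 (0.30) upward and TOB1 (-0.39) downward. Of 19 exosome genes 5 rose and 3 fell (adjusted p = 0.875), with EXOSC7 at 0.49, EXOSC6 at -0.73, EXOSC9 at -0.44 and TTC37 at -0.23, the last lost without control replicate 3 or LOC550643 siRNA replicate 2 (0.0638 and 0.0753). Of 17 factors of nonsense-mediated decay (NMD), 7 rose and 2 fell (adjusted p = 0.158); RNPS1 rose by 0.80, UPF3B by 0.70 and UPF1 by 0.40. Of 14 RNA interference genes 1 rose, DROSHA at 0.44, and 3 fell, AGO4 at -0.55, TNRC6A at -0.48 and AGO2 at -0.68 (list adjusted p = 0.875). The call of AGO2 was lost without LOC550643 siRNA replicate 1 or 2 (adjusted p = 0.0828 and 0.114), with DESeq2 (0.0989) and with the replicate number as a block (0.0528). For the decapping, exosome and RNA interference lists the median, mean and test differed in sign (medians -0.02, -0.02 and 0.04, means 0.001, -0.035 and -0.06, test upward).

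Lists of transcripts that decay pathways are known to act on did not pass either. Of 30 NMD-sensitive transcripts 10 rose, 2 fell and 18 did not pass, with a median log2 fold change of 0.09 (camera adjusted p = 0.0514); without control replicate 1 or LOC550643 siRNA replicate 3 the list passed (adjusted p = 0.0118 and 0.0166). ATF3 and PPP1R15A, which are also targets of the stress factor ATF4, rose by log2 0.82 and 0.69, TNFRSF10B, a death receptor, rose by 0.45, and SNHG16, a small nucleolar RNA host gene, fell from 480.0 to 201.1 CPM (-1.25). Of 44 AU-rich-element and immediate-early transcripts 9 rose and 8 fell (adjusted p = 0.555). JUN rose from 642.9 ± 63.8 to 1504 ± 278 CPM (log2 1.21, limma adjusted p = 5.8e-05), with JUND at 0.43 and ZFP36L2 at 0.53. Of 14 histone genes 2 rose, HIST1H2BK (0.32) and HIST1H3B (1.04), and the list did not pass (adjusted p = 0.181). The call of HIST1H2BK was lost on thinned libraries (adjusted p = 0.149), and that of HIST1H3B without control replicate 1 or 3 (adjusted p = 0.0547 and 0.0651) and without LOC550643 siRNA replicate 2 or 3 (0.0578 and 0.0622), and libraries selected for poly-A hold few of these mRNAs.

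Genes of stress responses and sugar metabolism were higher. Of 36 genes of the integrated stress response, 25 rose, 2 fell and 9 did not pass (median log2 0.35, camera adjusted p = 1.11e-05; adjusted p = 0.537 with an estimated correlation). ATF5, a transcription factor of this response, rose from 24.9 ± 3.74 to 70.7 ± 19.2 CPM (log2 1.48), ATF3 rose by 0.82 and PPP1R15A, which directs removal of the phosphate from eIF2α, by 0.69, while SARS, the cytosolic seryl-tRNA synthetase, fell from 443.4 ± 58.4 to 184.4 ± 30.7 CPM (-1.27). ATF5 overlaps MIR4751, IL4I1 and NUP62. ATF4 itself, looked up after the list was seen, was at -0.06 (limma adjusted p = 0.633). Of 19 cytosolic heat shock genes 12 rose and 1 fell (median 0.32, adjusted p = 0.000136; adjusted p = 0.537 with an estimated correlation), among them HSP90AA1, from 938.3 to 1822 CPM (0.94), its cochaperones AHSA1 (0.92), STIP1 (0.51) and FKBP4 (0.49). Of 24 genes of the unfolded protein response of the endoplasmic reticulum (ER), 11 rose and 3 fell (median 0.20, adjusted p = 0.0297; adjusted p = 0.537 with an estimated correlation). The ER chaperones CALR and HSPA5 rose by 0.91 and 0.51, and EDEM1 and SEL1L, which act in ER-associated degradation, fell by 1.12 and 0.80. Of 33 hypoxia and glycolysis genes 19 rose and 0 fell (median 0.27, camera adjusted p = 9.76e-05, and 0.537 with an estimated correlation). The members with the smallest p were the phosphofructokinases PFKL (0.94) and PFKP (0.45), PGAM1 (0.60) and the glucose transporter SLC2A3 (0.59).

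Genes of the interferon and double-stranded RNA response were lower. Of 29 measured, 0 rose, 16 fell and 13 did not pass (median log2 -0.43, camera adjusted p = 0.000136; adjusted p = 0.537 with an estimated correlation). TAP1, which moves peptides for MHC class I, fell from 39.2 ± 0.531 to 16.6 ± 2.27 CPM (-1.25), IFITM1 from 46.3 ± 3.36 to 25.8 ± 2.65 CPM (-0.85), IFI35 from 7.02 to 3.17 CPM (-1.14) and PSMB9 from 3.88 to 0.794 CPM (-2.26). TAP1 and PSMB9 are each listed at 8 positions, and TAP1 overlaps PSMB8-AS1 on the opposite strand. IFIH1, looked up after the list was seen, was at -0.01 and did not pass.

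In the cell cycle, 16 of 40 G2 and M phase genes rose and 2 fell (median log2 0.18, camera adjusted p = 0.00145; adjusted p = 0.537 with an estimated correlation). BIRC5 (0.57) and CDC20 (0.45) rose, and the kinases AURKA (-0.53) and CDK1 (-0.44) fell. Of 40 S phase and replication genes 13 rose and 6 fell (adjusted p = 0.158), with RRM2 at 0.74, MCM7 at 0.39, E2F2 at -0.49 and POLE2 at -0.47. None of the 6 list calls held with an estimated correlation between genes. The test compares a list with all other genes whatever their level. In the 10% of genes with the highest mean level the median log2 fold change was 0.16, and 40.6% of them rose. Beside 10000 random lists matched on mean level, a description added after the data were seen, 568 had a median as high as the G2 and M phase list (median of these lists 0.11) and 435 one as high as the unfolded protein response list (0.08). For heat shock 20 were as high (0.11), for hypoxia and glycolysis 13 (0.11) and for the integrated stress response 0 (0.14), and 0 were as low as the interferon list (-0.09). Among small lists that did not pass, 58 were as high as the keratin list (-0.21) and 217 as high as the histone list (-0.18). For the fibroblast list 315 were as low (-0.07). Of the 10 ways to split the 6 libraries into 3 and 3, 3 called 6 or more lists, the real one included, and the highest other called 7.

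The remaining lists did not pass with camera. With fry, which does not compare a list with other genes, the apoptosis, fibroblast and keratin lists passed (fry adjusted p = 0.0157, 0.0171 and 0.0344). Of 25 p53 targets 4 rose and 8 fell (camera adjusted p = 0.555), with XPC at log2 0.70, FAS at -0.93 and BAX at -0.46. Of 31 apoptosis genes 10 rose and 5 fell (adjusted p = 0.239); CASP8 rose by 0.69 and FADD by 0.59. Of 25 cholesterol genes 9 rose and 3 fell (adjusted p = 0.158), with INSIG1 at 0.88, FDPS at 0.76 and STARD4 at -0.59; without LOC550643 siRNA replicate 1 this list passed (adjusted p = 0.0168). Of 31 autophagy and lysosome genes 9 rose and 7 fell (adjusted p = 0.875), with ULK1 at 0.86, PSAP at 0.54, VPS18 at 0.41 and ATP6V0E1, a subunit of the vacuolar proton pump, at -1.43. Of 38 matrix and adhesion genes 10 rose and 10 fell (adjusted p = 0.555), with COL6A1 at 1.04, TIMP3 at 0.71, LAMC1 at -0.74 and TIMP2 at -1.19. Of 7 fibroblast markers 1 rose and 2 fell (adjusted p = 0.158), with PDGFRA at -1.13, COL3A1 at -0.53 and FBLN1 at 0.23. With all libraries thinned to the shallowest, the calls of PDGFRA (-0.68, adjusted p = 0.185) and COL3A1 (adjusted p = 0.0971) were lost. The call of FBLN1 was lost without control replicate 2 or 3 (adjusted p = 0.0597 and 0.0885) or LOC550643 siRNA replicate 2 or 3 (0.132 and 0.0624), when thinned (0.0663) or without a filter (0.0514), with library totals (0.109) or upper-quartile scaling (0.0578), and with the replicate number as a block (0.0532 with limma and 0.0502 with edgeR). Of 6 keratin epithelium markers 2 rose (adjusted p = 0.181), KRT17 at 1.57 and CLDN4 at 0.76, from 0.154 and 1.18 CPM in control libraries; without control replicate 3 the call of CLDN4 was lost (adjusted p = 0.0524), as it was on thinned libraries (0.168). The list of blood markers was not tested, with fewer than 5 members measured, and the list of mitochondrially encoded mRNAs had 0 members measured.

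Adjusted over the list alone, the number of members higher and lower was the same as over all genes for the decapping (6 and 3), integrated stress response (25 and 2), heat shock (12 and 1), hypoxia (19 and 0) and AU-rich-element (9 and 8) lists. It was 0 and 17 for interferon, 12 and 3 for the unfolded protein response, 17 and 2 for G2 and M phase, 11 and 2 for NMD-sensitive transcripts, 9 and 3 for deadenylation, 7 and 5 for exosome and 8 and 2 for NMD factor genes, each adjusted over the list alone. Adjusted over the list alone, the numbers were 5 and 9 for p53, 9 and 4 for cholesterol, 14 and 6 for S phase, 11 and 7 for apoptosis and 10 and 12 for matrix genes, and as over all genes for the RNA interference, histone, autophagy, fibroblast and keratin lists. For the AU-rich-element, autophagy and matrix lists the median was above 0 (0.03, 0.03 and 0.09) and the mean below it (-0.015, -0.012 and -0.012), with the test upward.

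**Figure D3:**
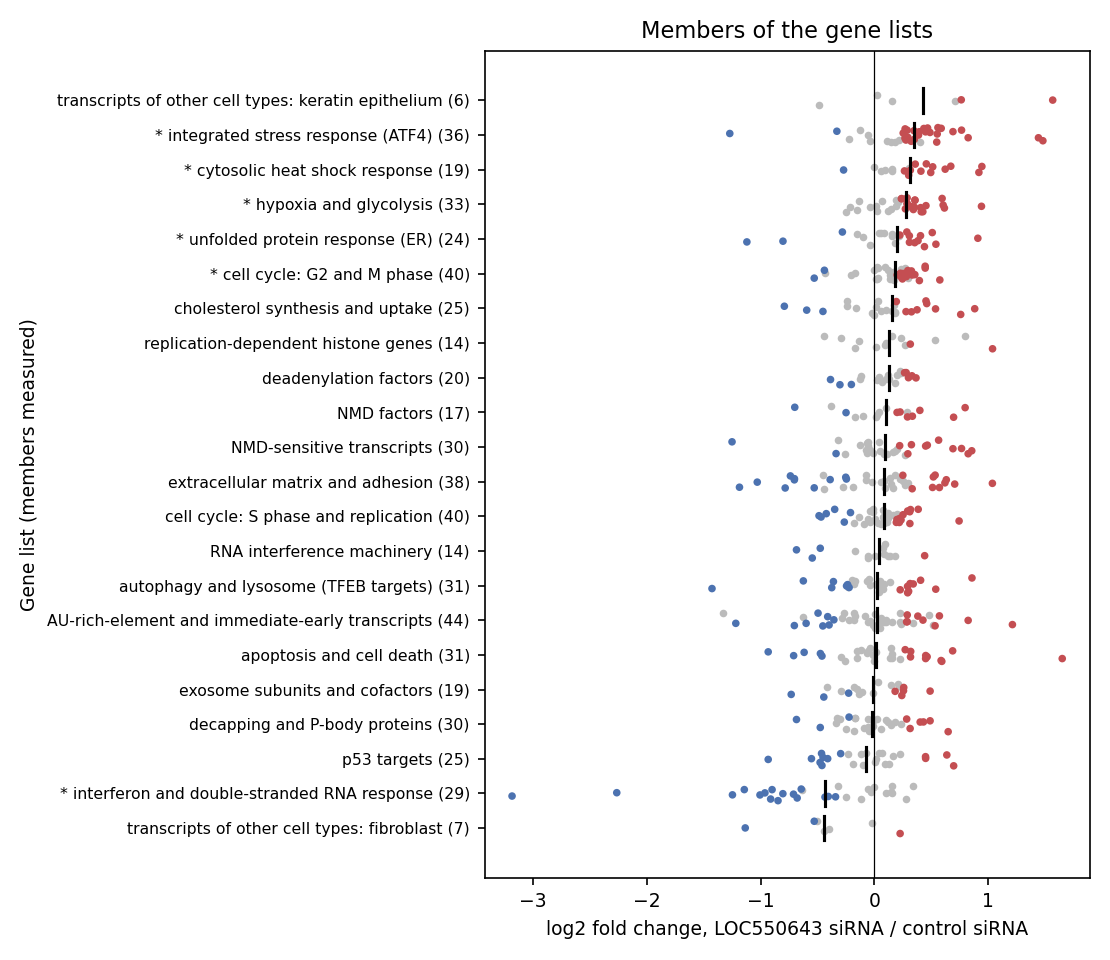
Log2 fold change of each measured member of 22 gene lists, with the number measured in parentheses; red and blue points passed at a limma adjusted p under 0.05, grey points did not, black bars are list medians and an asterisk marks a camera adjusted p under 0.05 with the preset correlation. The integrated stress response list lies at a median of 0.35 and the interferon list at -0.43.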

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

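Tests on thinned libraries (1 random draw), on read ends or pairs with edgeR's quasi-likelihood method without a block, as alternatives to limma, and after GC and length correction were chosen only after the data were seen. LINC01420 was lower in all 24 alternatives run, between -3.272 and -3.1. At an adjusted p of 0.01, 1770 genes were higher and 1751 lower, by the stricter threshold itself. With all libraries thinned to the shallowest, 1904 were lower (1986 higher), by fewer reads. With the correlation estimated, 0 gene lists passed. The p-values rose also where the estimated correlation was low. For the interferon list it was 0.032, and the unadjusted camera p went from 2.47e-05 to 0.0256. For the integrated stress response list it was 0.389, and the unadjusted camera p went from 5.07e-07 to 0.201. The cause of the loss was not tested. All other counts were within 1.5 times those reported. With each library left out in turn, genes higher ranged from 2048 to 2623, genes lower from 2237 to 2882, genes higher past a log2 fold change of 1 from 100 to 116, genes lower past it from 307 to 393, LINC01420 from -3.237 to -3.153, and lists passed from 6 to 7. GC and length correction gave 4167 higher and 2857 lower, a share of 59.3% higher, and the median of all genes moved from -0.02 to 0.04.

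Of 2551 values of 107 other named genes, 2482 kept direction and side, 56 lost the call, 7 gained it and 6 changed sign. The sign changes were in genes that passed in none of these fits: DCP1B at -0.004 (upper quartile), -0.051 (library totals), -0.163 (thinned) and from -0.016 to 0.06 with each library left out in turn, and EDC4 from -0.092 to 0.005 with each left out. Lists that did not pass in any alternative changed their tested direction when thinned, with medians of -0.046 (exosome), 0.049 (RNA interference) and 0.009 (autophagy), and in 2 or 3 of the fits with a library left out, over which the medians ran from -0.108 to 0.034 (exosome), -0.025 to 0.094 (RNA interference) and -0.006 to 0.039 (autophagy). In each of these the cause was not tested.

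Replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at 0.126, -0.416 and -0.215, and of the 6 libraries only LOC550643 siRNA replicate 1 correlated best with its own number. With the replicate block, limma gave 2671 genes higher and 2718 lower, 103 and 329 past a log2 fold change of 1, LINC01420 at -3.196 and 6 lists. Depth limits LOC550643 siRNA replicate 3, where 91 read ends stand behind the level of LINC01420; without that library 2452 genes were higher and 2532 lower.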

Other observations

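All tests in this part were chosen after the data were seen, apart from those of the shallow library and of the neuronal list, written down before their results; the repeats of the latter under other settings were also added later. Of 15 gene groups picked by symbol or function once fold changes were known, 2 passed. The ZNF zinc finger genes, many of them transcriptional repressors, tended upward. Of 443 measured, 112 rose and 31 fell (median log2 fold change 0.09, camera adjusted p = 0.011; adjusted p = 0.893 with an estimated correlation), and the median was 0.02 with library totals alone. ZNF25 was higher by log2 1.47 and ZNF616 by 1.15, and ZNF503 was lower, from 514.5 to 284.3 CPM (-0.86). Of 10000 random lists matched on level, 0 had a median as high as the ZNF genes. For the cytosolic ribosomal protein genes, which did not pass (camera adjusted p = 0.383), 0 had a median as low. Of 83 measured, 2 rose and 8 fell (median -0.07, against 0.16 for the matched lists), and the median was 0.04 without control replicate 1. For small nucleolar RNA host genes, which did not pass either, 429 had a median as low. Potassium channel genes, a family chosen because KCNC1 was among the largest falls, passed downward with KCNC1 included (64 measured, adjusted p = 0.0284; adjusted p = 0.893 with an estimated correlation). Without KCNC1 the call was at the edge of the threshold: of 63 measured, 3 rose and 16 fell (median -0.21, adjusted p = 0.0497; adjusted p = 0.893 with an estimated correlation). Low genes as a whole tended to fall, and 938 of 10000 random lists matched on level had a median as low (median of these lists -0.13), so the family did not stand clear of genes at its level. Its members KCNIP3 (-1.20) and KCNJ2 (-1.14) fell and KCNJ4 rose by 0.78. MRPS34, also looked up later and of the mitochondrial ribosome, rose from 110.0 to 243.2 CPM, and 15 members of that family rose and 13 fell (adjusted p = 0.584).

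Short words in 3′ UTRs went with the fold changes. On genes of the odd-numbered chromosomes and X, GCCTCCA was the 7-base word with the lowest z (-10.4, a difference of log2 -0.117 after UTR length, base composition and abundance, where 100 permutations reached at most 5.4 in size), and on genes of the even-numbered chromosomes the difference was -0.0678 (permutation p = 1e-05, the smallest these can give). Base composition is argued against by a median z of -0.21 over 183 other orders of these bases against -5.4 for the word, though a first, stricter bound, lowest of all orders, was missed because 1 order that overlaps the word, AGCCTCC, reached -5.7. A candidate explanation is pairing of siRNA seeds in the LOC550643 pool with unintended mRNAs. The higher word AGGAGAA (0.0434 on the even-numbered chromosomes, permutation p = 5e-05) may reflect the control siRNA in the same way. However, 2 of its 34 other orders reached as far, and GGAGAAA, which overlaps it, had a z of 5.8 against 4.1. Of genes with AGGAGAA 20.8% were called higher and 18.7% lower, against 19.8% and 19.9% of genes without it. The next higher word, CGGAGAG, did not hold (0.0395, permutation p = 0.142), and the siRNA sequences were not analysed here. Direct pairing with GCCTCCA and CCACTCT in the 3′ UTR alone is argued against as the source of all the falls. Of genes with neither word 16.5% were called lower, against 28.6% of genes with either, shares that were not corrected for UTR length. Indirect effects of such pairing, and pairing with other seeds of the pool, were not tested.

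Low genes tended to fall and abundant genes to rise. The median log2 fold change was -0.20 in the 10% of genes with the lowest mean level and 0.16 in the 10% with the highest, a difference of 0.358. The shallow LOC550643 siRNA replicate 3 is argued against as the source, since the difference was 0.351 without it. Background reads in the control libraries cannot be told apart from other sources: olfactory receptor genes, used as a gauge of such reads, had a ratio of LOC550643 siRNA over control read pairs, per depth, of 1.02 (exact 95% interval 0.843 to 1.23, counting error only), which includes both 1 and the 0.869 of the lowest 10%. A biological source, the silencing itself, was not tested.

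Neuronal and synaptic genes were looked at because KCNC1, NCAN and SYN1 (left out of the list) were among the largest falls. Of 75 measured members 28 were lower and 11 higher (median -0.20). The list did not pass (camera adjusted p = 0.0576, and 0.893 with an estimated correlation). The trend with abundance alone is argued against, since 0.13% of 10000 random lists matched on level had a median as low, and between 0.01% and 0.8% in the 23 alternatives other than thinning. With libraries thinned to the shallowest, which leaves fewer members, this weakened. In the first draw 1601 of 10000 matched lists were as low (median -0.105 over 68 members). The unthinned fold changes of these 68 members already had a median of -0.131, with 4.16% of matched lists as low, so a part of the weakening went with the members lost. In 20 further draws the share ran from 0.35% to 12.2% and was under 5% in 13. Such random lists do not carry correlation between genes. Nor were the shares adjusted over the gene groups picked once fold changes were known. Correlated members and the choice of the group thus stay open as sources. A part of the 3′ UTR words cannot be told apart, since the 41 members with neither word had a median of -0.142 (bootstrap 95% interval -0.358 to 0.03) and those with either had -0.12, no lower. REST, a repressor of such genes, was at 0.14 (limma adjusted p = 0.322).

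If AU-rich mRNAs had been spared from decay after the fall of LINC01420, fold change might have gone down with the GC content of the 3′ UTR. Across 13013 genes, which are not independent replicates, Spearman's rho was 0.0552 and Pearson's r 0.0451 (permutation p = 0.0001, the smallest these can give), weakly the other way. These fold changes were not corrected for abundance or for transcript GC content and length. GC content is also not a count of AU-rich elements, so the relation cannot decide whether such mRNAs were spared.

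The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 5793 genes and the highest other split 0, in 1 of 10 as many; past a log2 fold change of 1 it was 450 against 0, again 1 of 10. Every other split puts libraries of both siRNAs in each group. A difference between the siRNAs then adds to the spread within groups, so the lack of gene calls there does not measure chance. For gene lists, 3 of the 10 splits gave as many as the real 6, and the highest other gave 7.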
